A study of Homo sapiens with 18 samples.

How the data were processed

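The series holds 16 FLAG chromatin immunoprecipitation libraries from human iNeurons, neurons made from the i3 line of induced pluripotent stem cells by doxycycline induction and kept in sensory neuronal media. The cells carried FLAG-tagged ATF2 or JUN, each as a form labelled WT or a form labelled AA, and were treated with DMSO, the vehicle, or with vincristine, a drug that blocks microtubule assembly. What AA stands for is not given in the labels. There were 2 libraries per group of form and treatment, and 2 IgG libraries with no treatment label and no file of their own in what was used here.

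Each group was represented by 1 deposited peak list, 8 lists in all, whose names mark them as merged. The replicates were therefore pooled before peaks were called, and the spread between replicates was not available here. Reads had been aligned with Bowtie2 2.5.3, processed with SAMtools 1.19 and Picard 3.2.0, and peaks called with MACS2 2.2.7.1, per the submitters' processing notes. The same notes name deepTools 3.5.5, DiffBind 3.14.0 and DESeq2, whose output was not analysed here, and the genome build hg38. The lists have no header. Per the deposited values, a peak's fold is the authors' ratio of its summit pileup to the local control pileup, and a second pair of columns holds the deposited −log10 p and −log10 q of each peak. The lowest −log10 q in a list lay between 1.30 and 1.33, and the running numbers in the peak names showed that between 0 and 3 peaks per list had been taken out after calling. Fold and q are the authors' values and were used only to describe, rank or filter peaks within their own list. Which control library was used for which list is not given in the sources used here.

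Peaks on chromosomes 1 to 22, X and Y were used. A pair of lists was compared by overlap of at least 1 bp, counted from each side. Chance overlap was the mean of 100 shuffles of the peaks within their chromosomes, a reference that does not hold open chromatin constant. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and not the spread between cultures. No test between groups was possible with 1 list per group, so no p-values are given.

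Gene positions came from the RefSeq gene table of GRCh38.p14, which shares its coordinates with hg38. The table gives the start and end of 20037 protein-coding genes on these chromosomes but no strand, exons or sequence. The planned promoter window around the transcription start was therefore replaced by 1000 bp either side of either end of a gene, and a peak there is called a gene-end peak. Other peaks were counted as within a gene or intergenic, with introns and exons not told apart. The planned motif counts and the matching of random genes on promoter CpG content needed a genome sequence and were not run.

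A set of 17 gene lists, holding 401 genes of which 399 were matched, was fixed before the data were examined. The lists cover AP-1 and ATF/CREB factors, the DLK/LZK-JNK pathway, MAPK phosphatases, apoptosis, the integrated stress response, axon injury, immediate-early genes, the p53 response, the cytoskeleton, pan-neuronal genes, sensory neuron identity, pluripotency, glia, mesenchyme, the cell cycle, hepatocyte genes as an off-tissue control and ribosomal proteins as a housekeeping control. For each list, the share of members with a gene-end peak was placed among 10000 random lists of protein-coding genes of the same size, with ties counted in the middle. That percentile describes these lists of peaks and is not a test between conditions. A percentile outside the central 95% of random lists is called past the threshold. A total of 408 percentiles were computed, 24 for each gene list.

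Named genes followed a rule fixed before the data were examined. JUN and ATF3 were always named. For each comparison, the 10 protein-coding genes with the highest fold among gene-end peaks found in the first list only, and 10 for the second list only, could be named. From each gene list up to 4 members with such a peak could be added, together with all AP-1 and ATF/CREB genes and the 5 highest peaks of each list. Genes of the Y chromosome were left out.

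Depth was recovered from each list. MACS2 computes fold and p from the same 2 pileups, so the background pileup that gives the deposited −log10 p from the deposited fold, within 0.01, could be found for each list, and with it the factor by which treatment reads had been scaled to the control. Read numbers derived from it assume a genome size of 2.7 Gb, which is not given in the sources used here; the ratios between lists that share a control do not depend on it. On simulated values the background of 2.20 was recovered as 2.20 from 6000 peaks, a scaling factor of 0.70 as 0.701, and a simulated overlap of 40.0% of 5000 peaks as 40.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with seed 1.

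The alternatives were all contigs, merged peaks, a stricter q, 50% reciprocal overlap, summits within 200 bp, lists cut to the length of the shortest, gene-end peaks left out, windows of 500 bp and 3 kb, and any peak within 50 kb of a gene for the gene lists.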

Results

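FLAG-tagged ATF2 and JUN were mapped in human iNeurons under DMSO or vincristine. Both are bZIP transcription factors of the ATF and AP-1 families, and JUN is a target of the stress kinase JNK. The series title places the study in the DLK/LZK kinase cascade, which signals axon damage through JNK, and in neuronal apoptosis. The 8 lists, each called on 2 pooled libraries, held 34834 peaks for ATF2WT with DMSO and 57653 with vincristine, 30891 and 18341 for ATF2AA, 63049 and 43938 for JUNWT, and 43152 and 23820 for JUNAA. Median peak widths lay between 304 and 384 bp. The treatment reads behind each list, recovered from its fold and p values, came to 43.7 and 40.2 M reads for ATF2WT with DMSO and vincristine, 41.6 and 55.2 M reads for ATF2AA, 73.5 and 70.1 M reads for JUNWT, and 86.8 and 73.5 M reads for JUNAA. Control reads came to 30.6 to 30.8 M reads for the 4 ATF2 lists and 66.0 to 66.1 M reads for the 4 JUN lists, so list lengths of ATF2 and JUN rest on different depths. With 1 list per group, every difference reported here is a difference between 2 lists and has no replicate check.

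Merged over the 8 lists, the peaks formed 113760 regions, of which 3759 were listed in all 8 and 43797 in a single list. A further 3889 regions were in all 4 ATF2 lists and no JUN list, and 9493 in all 4 JUN lists and no ATF2 list. The highest peak by fold in both ATF2WT and both ATF2AA lists, and in JUNWT with vincristine, was the same intergenic site on chromosome 2 (70433971 to 70435602 in ATF2WT with DMSO), 12704 bp from an end of TGFA, a growth factor gene. Its fold within the ATF2AA DMSO list was 119. Other leading ATF2 sites lay inside SEMA5A, an axon guidance gene, RPTOR, a subunit of the mTORC1 kinase complex, RASGRF1 and ITPR2, each with an overlapping peak in all 8 lists. Leading JUN sites lay at gene ends of BUD31 and PDAP1 (chromosome 7, 99408132 to 99409658, fold 98.8 within JUNWT DMSO), GZF1 and PYCR1, a proline synthesis enzyme, and inside EIF2AK3, which encodes the stress kinase PERK, and TFRC, the transferrin receptor.

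The first comparison asked how vincristine changed the sites listed for each form. For ATF2WT the vincristine list was 1.66 times as long as the DMSO list, whereas the ratio was 0.594 for ATF2AA, 0.697 for JUNWT and 0.552 for JUNAA. Of the ATF2WT vincristine peaks, 26990, or 46.8% (95% interval 46.4 to 47.2%), had no overlapping DMSO peak. The corresponding shares were 13.3% (12.8 to 13.8%) for ATF2AA, 17.1% (16.8 to 17.5%) for JUNWT and 12.5% (12.1 to 12.9%) for JUNAA. In the other direction 11.8% of ATF2WT DMSO peaks were listed with DMSO only, against 48.9% for ATF2AA, 44.3% for JUNWT and 54.6% for JUNAA. Overlaps of shuffled peaks averaged 0.453 to 2.46% over these pairs. The 25% of peaks with the highest fold were mostly shared: 91.1% of them in ATF2WT with vincristine, and 99.7% in ATF2WT with DMSO, overlapped the other treatment. When every list was limited to its 18341 highest peaks, the share of vincristine peaks that overlapped DMSO peaks lay between 68.8 and 73.0% in all 4 forms. The highest peaks were thus shared to a similar degree in all forms. Lists of the same length give near-equal shares from either side by construction. This is therefore no check on the opposite directions of ATF2WT and the others. Below, a peak listed in 1 list only is a peak with no overlap in the compared list; where such a gene had another gene-end peak in the compared list, this is stated.

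**Figure D1:**
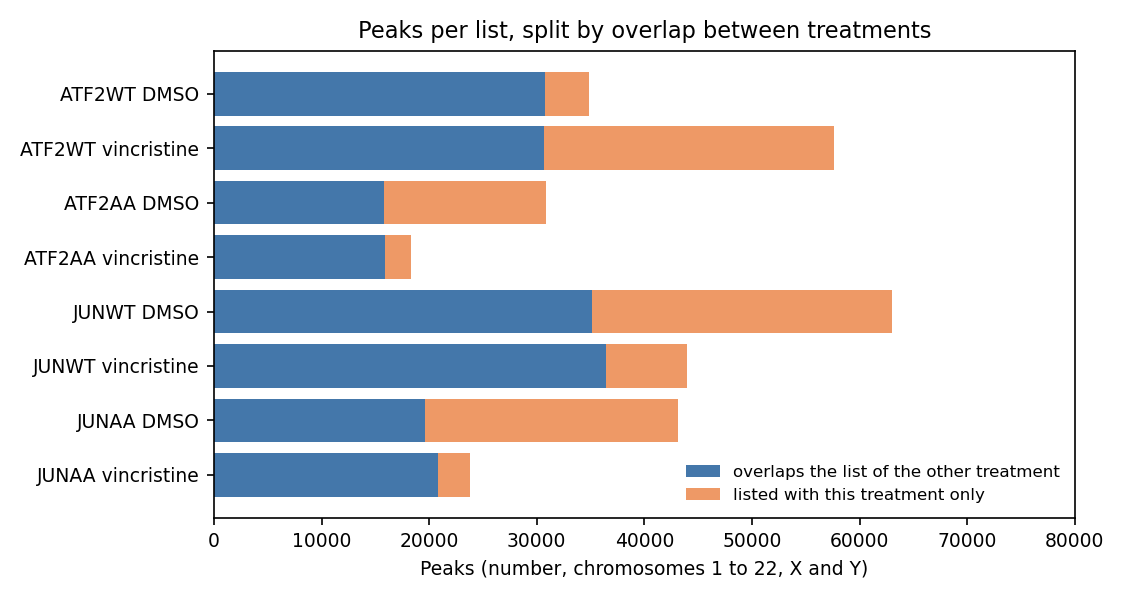
Number of deposited peaks per list (horizontal axis), split into peaks that overlapped the list of the other treatment by at least 1 bp (blue) and peaks that did not (orange). The vincristine list was the longer only for ATF2WT, with 57653 against 34834 peaks.

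The sites that ATF2WT was listed at with vincristine only were mostly not at gene ends. Of these sites 8.19% (2211 of 26990) lay near a gene end, against 35.2% of the 4108 DMSO-only sites and 15.2% of the sites shared with DMSO. The strongest vincristine-only gene-end peaks were at PPP1R12B (fold 12.1), OR2W1 (11.5), CCDC88A (10.3), PDK4 (10.2), a regulator of pyruvate dehydrogenase, and FOXO4 (9.28), a forkhead transcription factor. Stress genes with such a peak were DDIT3 (6.86), which encodes CHOP, the p53 target CCNG1 (6.30), the death receptor gene TNFRSF10B (5.34), and GADD45A (4.56). AP-1 and ATF genes with such a peak were JUND (5.30), ATF5 (5.08), BATF (4.62) and FOS (4.56). Of the genes named so far, DDIT3, JUND and ATF5 had another gene-end peak in the DMSO list. At the level of genes, 1731 had a gene-end peak in ATF2WT with vincristine only, 1120 with DMSO only and 5163 with both. The vincristine-only genes held 6 of 22 p53 response genes (AEN, CCNG1, GADD45A, SESN1, TIGAR and TNFRSF10B), which stood at percentile 99.5 of random lists, and 3 of 11 MAPK phosphatases (DUSP1, DUSP7 and DUSP10) at percentile 96.4. None of the 21 DLK/LZK-JNK genes was among the vincristine-only genes (percentile 7.26, with 8.64% for all genes), but 17 of them already had a gene-end peak with DMSO. The DMSO-only genes held 7 of 29 ribosomal protein genes, the housekeeping control, at percentile 99.9, and DMSO-only peaks lay at KLHDC9 (fold 11.9), CALCR (7.64), GSK3B (6.66), ATF4 (5.09) and CREB1 (4.28). Of these, GSK3B, ATF4 and CREB1 had another gene-end peak in the vincristine list.

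For ATF2AA 3873 genes had a gene-end peak with DMSO only, 237 with vincristine only and 3585 with both, from lists of different length; at equal lengths 4172 genes had one with DMSO and 3822 with vincristine. Peaks listed with DMSO only lay at ADRA1A (fold 12.8), DNAJC1 (11.2), RAB11B (10.6), GREB1L (10.5) and MYC (10.5), of which RAB11B and GREB1L had another gene-end peak with vincristine. DMSO-only genes included 9 of 21 DLK/LZK-JNK pathway genes (percentile 99.2), among them MAP3K12, which encodes DLK, MAPK9 and MAPK10, which encode JNK2 and JNK3, and MAPK8IP1, a JNK scaffold. They also included 9 of 25 pan-neuronal genes (percentile 97.48), such as SYT1, SCG2 and UCHL1, and 15 of 29 ribosomal protein genes, which as a housekeeping control stood at percentile 100.0. Counted only over genes with a DMSO gene-end peak, the DMSO-only genes were 9 of 18 DLK/LZK-JNK, 9 of 17 pan-neuronal and 15 of 24 ribosomal protein genes. For all genes they were 3873 of 7458. For DLK/LZK-JNK and pan-neuronal genes the percentile thus reflects how often they had a DMSO peak, not a greater loss with vincristine. Vincristine-only ATF2AA peaks lay at GRAMD2B (7.101), ZNF71 (6.81), POP7 (6.21), the p53 targets FDXR (4.96) and PHLDA3 (4.60), and ADCYAP1 (4.84), a neuropeptide gene induced by nerve injury, of which PHLDA3 had another gene-end peak with DMSO.

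JUNWT and JUNAA both had shorter lists with vincristine, while most genes kept a listed gene-end peak. For JUNWT 11776 genes had one with both treatments, 1470 with DMSO only and 243 with vincristine only, and for JUNAA the numbers were 9101, 3771 and 91. JUNWT peaks listed with DMSO only were mostly not at gene ends, with 8.72% near a gene end against 31.3% of the shared ones. They included peaks at CDIN1 (fold 17.4), NLRP12 (10.7), ITGB7 (10.6), TLX3 (6.14), a sensory neuron transcription factor, and DDIT4 (4.86), a stress-induced inhibitor of mTORC1; TLX3 and DDIT4 had another gene-end peak with vincristine. Those listed with vincristine only included TRERF1 (6.92), EIF2B2 (6.25), HGH1 (6.12) and BCL2L1 (2.91), which encodes an inhibitor of apoptosis, and all of these but HGH1 had another gene-end peak with DMSO. JUNAA peaks listed with DMSO only lay at CCDC198 (14.2), GNAI2 (10.5), SCG2 (8.11), SLC7A11 (5.93), a cystine transporter, STAT3 (4.76) and GADD45A (4.21), of which GNAI2, STAT3 and GADD45A had another gene-end peak with vincristine. Gene-end peaks were listed for JUNAA with DMSO only at 8 of 20 cell cycle genes (percentile 98.4) and at 6 of 26 immediate-early genes (percentile 71.5), among them NPAS4 (3.92) and NR4A2 (3.83). Vincristine-only JUNAA gene-end peaks were led by APOO (4.97), GZMB (4.45) and GALNT13 (4.17), and APOO had another with DMSO. JUNWT vincristine-only peaks overlapped the ATF2WT vincristine list in 39.9% of cases, against 18.3% of the JUNWT DMSO-only peaks. Against the ATF2WT DMSO list the shares were 29.2 and 14.1%, so the gap was not particular to ATF2WT sites listed with vincristine. JUNWT peaks shared between treatments overlapped the ATF2WT vincristine list in 35.2% of cases in the vincristine list and 36.5% in the DMSO list.

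The second comparison set the AA form of each factor against its WT form. With DMSO, 65.4% (64.9 to 65.9%) of ATF2WT peaks overlapped ATF2AA peaks and 73.4% (72.9 to 73.9%) of ATF2AA peaks overlapped ATF2WT peaks. With vincristine the shares were 29.7% (29.4 to 30.1%) and 93.9% (93.5 to 94.2%), with 40511 peaks listed for ATF2WT only and 1128 for ATF2AA only. Those 1128 peaks stood apart by position: 57.6% (54.7 to 60.5%) lay near a gene end, against 16.6% of the ATF2AA peaks shared with ATF2WT and 9.83% of the ATF2WT-only peaks. They also overlapped the JUNWT vincristine list in 81.2% of cases and the JUNAA DMSO list in 80.7%, against 54.0 and 31.0% of the shared peaks. For the JUNAA vincristine list the shares were 69.2 and 26.4%. Of all ATF2AA vincristine peaks that overlapped that list, 52.0% lay near a gene end, against 5.71% of the rest. These shares were not compared at matched positions. With DMSO the ATF2AA-only peaks lay near a gene end in 30.8% of cases and the ATF2WT-only peaks in 10.6%. At equal lengths the vincristine shares were 63.8% of ATF2WT and 64.3% of ATF2AA peaks. Lists cut to the same length give near-equal shares from either side by construction, so this is no check on the difference between the directions.

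The strongest ATF2AA-only gene-end peaks with DMSO were at DUSP8 (chromosome 11, 1571044 to 1573136, fold 33.6), a phosphatase acting on JNK and p38, at JUN itself (fold 30.2), and at CIC (27.1), LMOD1 (24.6), GNAI2 and SEMA3B (23.7), RNASEK (20.2) and CDC25C (19.8). DUSP1 (15.7), AEN (12.4), DDIT3 (9.97), HRK (9.97), a pro-apoptotic BH3-only gene of the JNK pathway in neurons, HOMER1 (9.11), STMN4 (8.79), FLRT3 (6.96) and MAFF (6.94) also had such peaks. Of these genes, LMOD1 and DDIT3 had another gene-end peak in the ATF2WT DMSO list. With vincristine ATF2AA-only peaks lay at KLF6 (chromosome 10, 3784778 to 3785577, fold 26.4), a regeneration-associated factor, DUSP8 (18.2), DTNA (17.4), JUN (16.0), CIC (14.6), LIN7B (12.6), BTG2 (7.64), CASP9 (6.56), MAP2K7 (6.27), which encodes the JNK kinase MKK7, and HRK (5.44). The ATF2WT vincristine list had 2 other KLF6 peaks, at 3784161 to 3784570 and 3785594 to 3785897, on either side of this one, and other gene-end peaks at CIC, BTG2 and CASP9. By gene, ATF2AA-only genes with DMSO held 8 of 22 p53 response genes (percentile 99.9), 9 of 34 axon injury genes (percentile 99.5), 6 of 26 AP-1 and ATF/CREB genes (percentile 96.8; FOS, FOSB, JDP2, JUN, MAF and MAFF) and 7 of 33 apoptosis genes (percentile 96.2; APAF1, BAX, BCL2, CYCS, HRK, MCL1 and PMAIP1). The DLK/LZK-JNK pathway had 3 of 21 (percentile 71.8) and the MAPK phosphatases 3 of 11 (percentile 93.9). With vincristine they held 4 of 34 axon injury genes (percentile 99.5; FLRT3, ITGA7, SMAD1 and STMN4), 3 of 22 p53 genes (percentile 99.1; FDXR, PPM1D and XPC), 3 of 26 AP-1 and ATF/CREB genes (percentile 98.4; FOSB, JUN and MAFF) and 3 of 33 apoptosis genes (percentile 97.2; BAX, CYCS and HRK), with 2 of 21 DLK/LZK-JNK genes (percentile 94.6) and 1 of 11 MAPK phosphatases (percentile 86.3). The ribosomal protein control stood at percentile 94.7 with DMSO and 98.1 with vincristine in the same classes.

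ATF2WT-only gene-end peaks with DMSO lay at GON7 and UBR7 (a single peak, fold 10.3), PCDH20 (8.08), TNFRSF21 (7.94), which encodes death receptor 6, HOXD11 (7.47), GAL (5.64) and MAP3K5 (4.89), which encodes the kinase ASK1; GON7, UBR7 and TNFRSF21 had another gene-end peak for ATF2AA. With vincristine they lay at HOXD11 (14.4), GON7 and UBR7 (14.3), PLEKHA4 (13.7), HIC1 (12.3), UBQLN2 (12.5), CHGA (7.13), CREB3 (7.04), MAPK14 (6.30), MAP3K12 (5.27), MAPK8IP1 (5.22), STMN2 (5.05), DDIT3 (5.02) and NMNAT2 (4.56), an axon survival factor, and of these DDIT3 had another for ATF2AA. The ATF2WT-only genes with vincristine held 7 of 21 DLK/LZK-JNK genes (percentile 95.6) and 12 of 29 ribosomal protein genes (percentile 99.8). Of the 15 DLK/LZK-JNK genes with an ATF2WT vincristine gene-end peak, 7 were ATF2WT-only, against 3569 of 6894 for all genes.

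**Figure D2:**
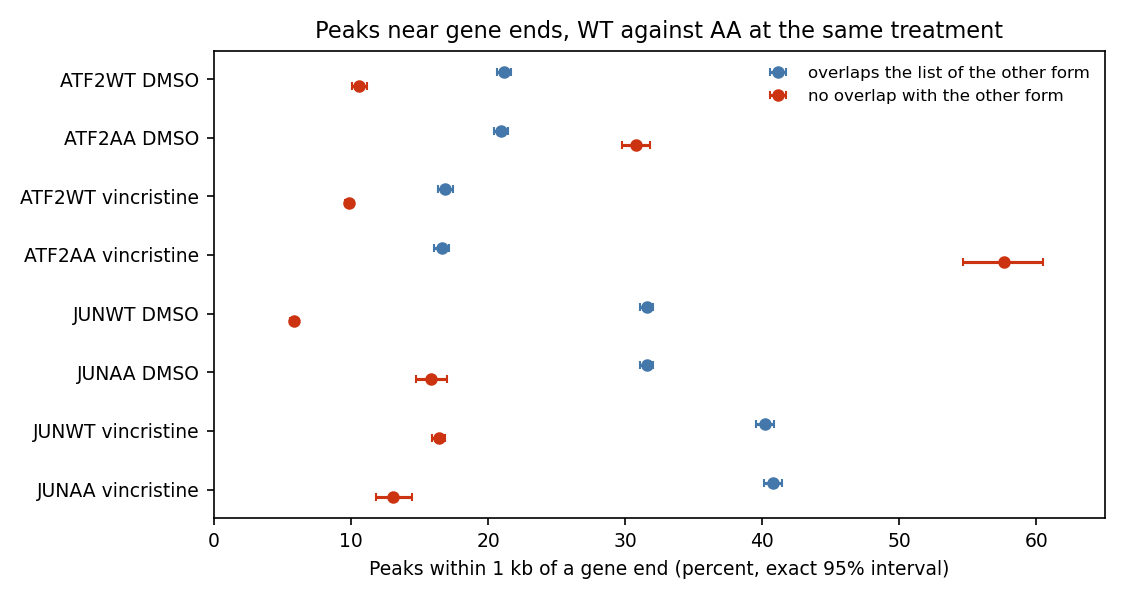
Share of peaks within 1 kb of either end of a protein-coding gene (horizontal axis, percent, with exact 95% binomial intervals) for peaks that overlapped the list of the other form at the same treatment (blue) and peaks that did not (red). ATF2AA peaks with no ATF2WT counterpart reached 57.6% with vincristine, and JUNWT peaks with no JUNAA counterpart 5.83% with DMSO.

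For JUN the AA list was the shorter with both treatments. With DMSO 90.2% (89.9 to 90.5%) of JUNAA peaks overlapped JUNWT peaks and 59.98% of JUNWT peaks overlapped JUNAA peaks. With vincristine the shares were 89.3% (88.9 to 89.7%) and 46.1% (45.6 to 46.5%). At equal lengths they were 81.3 and 80.6% with DMSO and 71.3 and 69.2% with vincristine, near-equal from either side by construction and so no check on the difference between the directions. The 25233 JUNWT-only peaks with DMSO were mostly not at gene ends, with 5.83% there against 31.6% of the shared ones, and 29.2% of them overlapped the ATF2WT DMSO list. Only 3.88% of the 4222 JUNAA-only peaks did. JUNAA-only peaks were mostly of low fold. Of the 25% of JUNAA DMSO peaks with the lowest fold 72.1% overlapped JUNWT, against 99.9% of the highest 25%. The shares of JUNWT peaks that overlapped JUNAA were 27.7 and 96.3%. Named JUNWT-only peaks with DMSO lay at CR2 (fold 8.65), PAICS (7.95), GALNT13 (7.704), RAB18 (6.61), FAP (4.41) and DDIT3 (4.28), and with vincristine at SCN1A (8.43), a neuronal sodium channel gene, OGT (7.18), EMX2 (7.01), SCG2 (6.40), TP53 (5.56), DUSP6 (5.13), GADD45A (4.92), SLC7A11 (4.71), ARC (4.08) and BCL2L11 (3.97), which encodes the pro-apoptotic protein BIM. JUNAA had another gene-end peak at RAB18 and DDIT3 with DMSO and at TP53, DUSP6, GADD45A and ARC with vincristine. JUNAA-only peaks were led by TRPM1 (5.62), EIF2B2 (5.56) and SPIN3 (5.42) with DMSO and by ITGB7 (4.86), NLRP12 (4.65) and TBX4 (4.24) with vincristine, and JUNWT had another at EIF2B2, SPIN3 and TBX4. Of the immediate-early genes, 2 of 26 (KLF2 and NR4A1) had a gene-end peak in JUNAA only with vincristine, at percentile 98.8. No DLK/LZK-JNK gene was JUNAA-only with either treatment, against 1.55% of all genes with DMSO and 0.89% with vincristine. With 20 of 21 already listed for JUNWT under each treatment, this was nearly fixed in advance. With vincristine 1 of 21 was JUNWT-only, against 15.0% of all genes.

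The third comparison set ATF2 against JUN. With DMSO 47.7% (47.1 to 48.2%) of ATF2WT peaks overlapped JUNWT peaks, against 2.07% for shuffled peaks, and 25.1% of JUNWT peaks overlapped ATF2WT peaks. With vincristine the shares were 28.4% (28.0 to 28.7%) and 36.0% (35.6 to 36.5%). For the AA forms 36.3% of ATF2AA peaks with DMSO and 29.0% with vincristine overlapped the JUNAA list. Lists cut to 18341 peaks gave 15.2% with DMSO and 17.6% with vincristine for ATF2WT against JUNWT, and 20.9 and 23.2% for ATF2AA against JUNAA. The order of the treatments thus turned for the WT and the AA forms. Away from gene ends, at full length, the ATF2AA shares were 17.7 and 16.9%. Shared sites were richer in gene ends: 33.8% of ATF2WT DMSO peaks that overlapped JUNWT lay there, against 2.68% of those that did not.

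JUNWT gene-end peaks with DMSO that no ATF2WT peak overlapped included GZF1 (fold 79.5), PYCR1 (63.8), CLIC1 (61.0), CHAC1 (52.8), a glutathione-degrading enzyme induced in the integrated stress response, MBNL2 (52.2), EIF2S3 (51.8), SERPINE1 (41.2), CYCS (40.3), which encodes cytochrome c, HRK (34.9), DUSP8 (33.0), GADD45B (27.6), TNFRSF12A (24.3), FOSB (20.3) and MAFF (19.6). With vincristine they included PDAP1 and BUD31 (a single peak, 30.1), MBNL2 (28.0), SERPINE1 (26.1), S100A2 (25.7), PYCR1 (25.5), VIM (23.6), CHAC1 (22.5), GADD45B (20.3), HRK (20.0) and CYCS (18.2). ATF2WT had another gene-end peak at CLIC1 with DMSO and at CHAC1 with vincristine. No gene list was tested for these classes. In JUNAA against ATF2AA with DMSO, MBNL2 (40.8), NTMT1 (38.6), VIM (37.6), IARS1 (35.0) and SERPINE1 (29.3) led, and with vincristine PYCR1 (21.2), S100A2 (18.8), CHAC1 (18.6) and SERPINE1 (17.5). ATF2 gene-end peaks that no peak of the compared JUN list overlapped lay at CNP (17.0), ZMYND12 (13.4), ISX (13.3) and CD48 (13.0) for ATF2WT with DMSO, C6orf15 (19.4), GDA (17.3), TIGAR (10.3), CCNG1 (6.30) and PRDM12 (5.30) for ATF2WT with vincristine, JUN (30.2), SEC14L3 (18.8) and SYP (9.06) for ATF2AA with DMSO, and SLC28A2 (23.5), TRMT5 (22.1) and PAX6 (13.9) for ATF2AA with vincristine. The compared JUN list had another gene-end peak at CNP, ZMYND12, TIGAR, CCNG1, JUN, SYP and TRMT5. Of 20037 genes, 6064 had a gene-end peak in both WT lists with DMSO, where independent lists of these sizes would share 4154. A total of 7182 had one in JUNWT only and 219 in ATF2WT only.

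At JUN (chromosome 1, 58780791 to 58784047) the lists differed by form. A peak across the higher-coordinate gene end was listed for ATF2AA with DMSO (58783320 to 58785141, fold 30.2) and with vincristine (58783365 to 58784722, fold 16.0). Neither ATF2WT list and none of the 4 JUN lists had a peak across that end. Both ATF2WT lists had a peak 15836 and 15843 bp outside that end (fold 12.1 with DMSO and 16.3 with vincristine), a place also listed for both ATF2AA and both JUNWT lists and for neither JUNAA list, and ATF2WT with vincristine and ATF2AA with DMSO had a further peak about 58820205. All 4 JUN lists had a peak inside the gene, at 58782115 to 58783070 in JUNWT with DMSO, where the recovered control pileup was 172 to 192 times the background of the list, a limit on what a JUN list can show at this gene. This inner peak reached into the 1 kb window of the gene end in JUNWT with DMSO and in both JUNAA lists but not in JUNWT with vincristine, so the counts of genes with a gene-end peak include JUN for those 3 JUN lists. ATF2AA with DMSO had a peak in the same place with a control pileup of 9.01 times background.

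**Figure D3:**
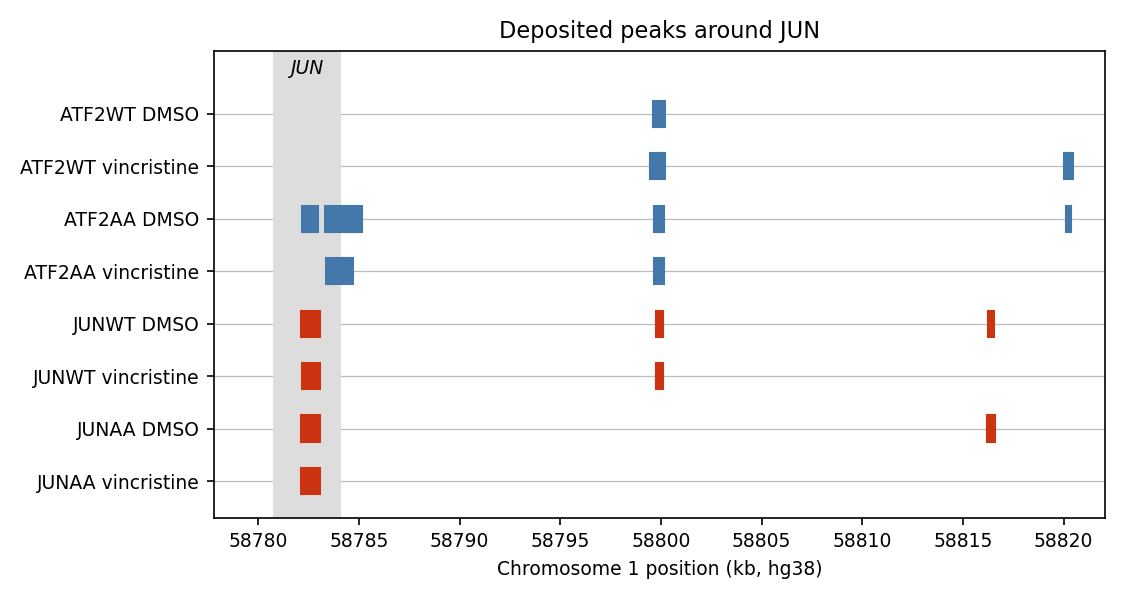
Deposited peaks around JUN on chromosome 1 (horizontal axis, kb, hg38), with ATF2 lists in blue, JUN lists in red and the gene shaded. Peaks across the gene end at 58784047 were listed for ATF2AA with both treatments, and the 4 JUN lists had a peak inside the gene.

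At ATF3 (chromosome 1, 212565407 to 212620777), a stress-induced ATF family gene, the JUN lists were the fuller. Within 50 kb of the gene there were 11 and 9 peaks for JUNWT with DMSO and vincristine and 10 and 6 for JUNAA, against 2 and 5 for ATF2WT and 3 and 2 for ATF2AA. The highest peaks of JUNWT with DMSO were inside the gene at 212607615 to 212609903 (fold 35.7) and outside its lower-coordinate end at 212558280 to 212559541 (33.5). Both places were also listed for ATF2AA with DMSO (8.25 and 14.0) and with vincristine (4.90 and 7.79). ATF2WT with DMSO had only the second of these (4.52), and ATF2WT with vincristine a peak at 212609326 to 212609611 (3.503). A peak across the lower-coordinate end of ATF3 was listed for JUNWT with both treatments (7.29 with DMSO) and for JUNAA with DMSO, and in no ATF2 list; the JUNAA vincristine list had a peak just outside that end, at 212565111 to 212565379.

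Position relative to genes separated the lists. The share of peaks near a gene end was 17.5% (17.1 to 17.9%) for ATF2WT with DMSO and 11.9% (11.7 to 12.2%) with vincristine, 23.6 and 19.1% for ATF2AA, 21.3 and 27.4% for JUNWT and 30.1 and 37.8% for JUNAA. Intergenic peaks made up 43.9 and 47.7% of the ATF2WT lists and 33.5 and 28.9% of the JUNAA lists. Genes with a gene-end peak numbered 6283 and 6894 for ATF2WT, 7458 and 3822 for ATF2AA, 13246 and 12019 for JUNWT and 12872 and 9192 for JUNAA. At equal lengths the order of the treatments turned for ATF2WT (2522 and 1398), JUNWT (5343 and 5559) and JUNAA (6483 and 6767), and for ATF2AA the numbers were 4172 and 3822. At equal lengths ATF2AA with DMSO kept a higher share near gene ends than ATF2WT with DMSO, at 20.3 against 12.2%.

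DLK/LZK-JNK, cytoskeletal and integrated stress response genes carried gene-end peaks more often than random genes in all 8 lists. In the ATF2WT DMSO list 17 of 21 DLK/LZK-JNK genes had one, among them MAP3K12, MAP2K4, MAPK8, MAPK8IP3 and SPAG9, at percentile 100.0 and with 31.4% for all genes. The counts were 15 with vincristine, 18 and 10 for ATF2AA, 20 and 20 for JUNWT and 20 and 19 for JUNAA. At equal lengths this percentile fell to 92.4 and 69.3 for ATF2WT with DMSO and vincristine and to 91.0 for ATF2AA with DMSO, no longer past the threshold. When any peak within 50 kb counted it fell to 90.4 for ATF2WT with vincristine, 88.0 and 93.1 for JUNWT and 94.5 for JUNAA with DMSO. Where most genes have a peak within 50 kb, ties can keep even a fully listed gene list below the upper threshold. High calls that ended within 50 kb, here and below, are therefore no evidence that an enrichment was lost. The cytoskeletal call ended at equal lengths for ATF2WT with DMSO (95.4) and vincristine (42.5) and within 50 kb for ATF2WT with vincristine (84.5) and JUNWT with DMSO (95.2). Integrated stress response genes were no longer past it in any list when any peak within 50 kb counted, and in ATF2WT with DMSO their call also ended at equal lengths. Of 26 AP-1 and ATF/CREB genes, 12 had one in ATF2WT with DMSO (percentile 94.1) and 15 with vincristine (99.3), 17 and 11 in ATF2AA, 24 and 22 in JUNWT and 23 in both JUNAA lists. The ATF2WT vincristine call ended both at equal lengths and within 50 kb, while ATF2WT with DMSO was newly past the threshold within 50 kb. For the next groups, values are for ATF2WT and then JUNWT, both with DMSO. Cytoskeletal genes had 20 and 34 of 35 (percentiles 99.9 and 100.0), integrated stress response genes 13 and 21 of 24 (98.9 and 98.9), pan-neuronal genes 12 and 22 of 25 (96.0 and 99.2) and immediate-early genes 10 and 25 of 26 (77.6 and 99.98). Further, p53 response genes had 8 and 20 of 22 (69.6 and 99.6), MAPK phosphatases 4 and 11 of 11 (64.2 and 99.4), axon injury genes 11 and 27 of 34 (55.8 and 94.9) and apoptosis genes 9 and 28 of 33 (31.5 and 99.01). Sensory neuron identity genes had 6 and 19 of 29 (11.0 and 46.6). Ribosomal protein genes, the housekeeping control, had 21 and 29 of 29, both at percentile 100.0. Of groups of other cell types, some were low at gene ends past the threshold and some were not: 2 and 7 of 18 pluripotency genes (percentiles 3.07 and 1.09), 2 and 9 of 20 glial genes (1.72 and 2.76), 1 and 10 of 20 mesenchymal genes (0.26 and 6.98), and 0 and 7 of 25 hepatocyte genes (0.0 and 0.02). Past it were the glial, mesenchymal and hepatocyte genes in ATF2WT and the pluripotency and hepatocyte genes in JUNWT, and at equal lengths the glial (39.4) and mesenchymal (16.4) calls in ATF2WT ended. So few genes were listed for ATF2WT at equal lengths that 20 genes with no member listed would not pass the lower threshold. The end of these calls was thus fixed in advance and is no check on them. Within 50 kb the mesenchymal (9.96) and hepatocyte (59.5) calls in ATF2WT and the pluripotency (7.02) and hepatocyte (14.8) calls in JUNWT ended. In JUNWT with DMSO the calls for MAPK phosphatases, p53 response and apoptosis genes ended both at equal lengths (96.8, 84.6 and 80.2) and within 50 kb (76.5, 88.9 and 94.8), while axon injury genes rose to 99.8 at equal lengths. For the glial genes in ATF2WT with DMSO the direction turned, to percentile 97.8, when any peak within 50 kb counted. Cell cycle genes had 1 and 17 of 20 (0.30 and 96.5), and the first call ended at equal lengths (16.1), which for 20 genes was likewise fixed in advance. Because the housekeeping control also stood high, a high percentile is not specific to stress or neuronal genes. The calls for this control in ATF2WT and JUNWT with DMSO themselves ended at equal lengths and within 50 kb.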

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

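The control pileup test for JUN below and the carry-over test at the JUN gene end itself were written after the result was seen, and the other tests were written before. ATF2WT and ATF2AA moved in opposite directions under vincristine, with 1.66 and 0.594 times as many peaks as with DMSO; with 1 list per group this difference was not tested. Read depth did not account for it, since for both ATF2 forms the longer list came from the shallower pooled library. ATF2WT had 43.7 M reads with DMSO and 40.2 M with vincristine, and ATF2AA 41.6 and 55.2 M. Over all forms the longer list came from the deeper library in 2 of 4 pairs, those of JUNWT and JUNAA. Depth is therefore not set aside for the shorter JUN lists with vincristine. Of the shorter list of a pair, 82.9% (JUNWT) to 88.2% (ATF2WT) overlapped the longer list, which argues against shorter lists that hold only sites of the longer. Under the stricter q the share was 91.3, 89.6, 90.7 and 94.7% for ATF2WT, ATF2AA, JUNWT and JUNAA, so this rests largely on peaks near the deposited threshold and is weak. Differences in the quality of single immunoprecipitations, which no pooled list can show, and a biological effect of vincristine on ATF2 both remain untested.

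The control libraries carried a signal of their own inside JUN, data that no comparison of the report uses: the control pileup at the peak inside the gene was 172, 176, 192 and 185 times background in JUNWT with DMSO and vincristine and JUNAA with DMSO and vincristine. A candidate explanation is DNA of the introduced JUN sequence, which was not tested. Inside ATF2, at 175118031 on chromosome 2, the 4 ATF2 lists had a peak with a control pileup of 15.9 to 18.8 times background. No JUN list had a peak at that place. Spread over 10 kb, this control signal was at the lowest 15.7 times background, so a peak across the JUN gene end needed a pileup of 109 to 114 reads, which 93.3 to 99.3% of gene-end peaks in those lists did not reach. The missing JUN gene-end peak in the JUN lists therefore may be a limit of the control and is no evidence that JUN was absent there. Carry-over of a JUN library into the ATF2AA DMSO library was also examined. Other peaks listed for ATF2AA only held a median of 13.4 times the reads it would bring, above the bound of 5 set against it. These peaks had all been called in ATF2AA, while carry-over was put at 1.985% of the JUNWT DMSO reads. A high ratio was thus nearly fixed by that selection, and it is no evidence against carry-over. Only peaks that overlapped a JUNWT peak could be tested there, and the JUN gene-end peak was not among them. At the JUN gene end itself, the JUN lists were taken to stand just short of a call. The control pileup of the peak inside JUN was used, where a call needed a pileup of 907 to 989. That is far above the 109 to 114 given above and favours carry-over. The 148.1 recovered reads were 7.39, 3.52, 7.18 and 3.54 times the most that JUNWT and JUNAA with DMSO and vincristine would bring. A ratio above 5 for all 4 had been set as evidence against it and was not met. The most carried reads, at 42.1, still fell short of the recovered reads, which argues against carry-over as the only source of this peak. A biological explanation was not tested.

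The control pileup at the SYN1 gene end, also outside the comparisons, was 71.9, 69.0, 69.7 and 69.3 times background in the ATF2WT and ATF2AA lists with DMSO and vincristine. In the JUNWT and JUNAA lists it was 150, 150, 150 and 150 times (150.29, 149.83, 150.19 and 149.53). The treatment reads recovered there were 860 and 733 for ATF2WT, 4158 and 2901 for ATF2AA, 13151 and 7173 for JUNWT and 14155 and 6367 for JUNAA. The peak itself was not left out of the counts: SYN1, a pan-neuronal gene, was counted with a gene-end peak in all 8 lists.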

How the results depend on the processing

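No paired analysis was possible because each group had 1 pooled list. Leaving out a replicate, motif counts and CpG-matched random genes were not run, since the replicates were pooled and no sequence was at hand; leaving out peaks of high control pileup was chosen after seeing the data. The direction of the treatment ratios was kept under all contigs, a stricter q and without peaks of high control pileup; under the stricter q they were 1.74, 0.532, 0.610 and 0.389 for ATF2WT, ATF2AA, JUNWT and JUNAA. For every change below the cause was not tested, except that a stricter q or an equal length leaves fewer peaks and a narrower or wider window fewer or more near gene ends by construction. Lists are in the order ATF2WT, ATF2AA, JUNWT, JUNAA, with DMSO before vincristine. Peak counts under the stricter q were 15016, 26157, 13034, 6936, 37425, 22826, 26074 and 10145.

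Overlap of vincristine with DMSO peaks for ATF2WT, ATF2AA, JUNWT and JUNAA was 48.8, 76.6, 67.4 and 56.6% at 50% reciprocal overlap, 50.3, 80.7, 69.7 and 70.2% with summits within 200 bp, 52.3, 89.6, 90.7 and 94.7% under the stricter q, 73.0, 68.8, 72.5 and 69.1% at equal lengths and 51.1, 85.2, 76.5 and 78.4% away from gene ends. In the same order of settings, ATF2WT with ATF2AA under vincristine gave 24.8, 28.0, 25.3, 63.8 and 28.0%, JUNWT with JUNAA under vincristine 34.0, 39.6, 42.4, 69.2 and 37.9%, ATF2WT with JUNWT under DMSO 28.8, 36.6, 34.2, 15.2 and 37.2%, and under vincristine 17.5, 21.1, 17.6, 17.6 and 20.7%. Shares near gene ends were 14.8, 9.75, 20.6, 16.4, 19.0, 24.3, 27.0 and 33.4% within 500 bp, and 23.1, 17.4, 29.0, 24.7, 27.5, 34.0, 36.7 and 44.5% within 3 kb. At equal lengths they were 12.2, 6.74, 20.3, 25.3, 26.4, 30.8 and 34.0%, with ATF2AA under vincristine, the shortest list, unchanged. Genes with a gene-end peak at equal lengths were 2522 and 1398 for ATF2WT, 4172 and 3822 for ATF2AA, 5343 and 5559 for JUNWT and 6483 and 6767 for JUNAA, so the order of the treatments turned for ATF2WT, JUNWT and JUNAA. JUNAA with JUNWT gave 76.5% with DMSO and 62.8% with vincristine at 50% reciprocal overlap and 81.3 and 71.3% at equal lengths, where JUNWT with JUNAA gave 80.6 and 69.2%. Of the 408 percentiles, only the 136 for genes with a gene-end peak in a whole list were recomputed under other settings. Those for DMSO-only, vincristine-only, WT-only and AA-only genes were not, so how far they depend on these settings was not tested. Of the 136, 86 were past the threshold. Of these, 64 no longer were when any peak within 50 kb counted and 34 at equal lengths. Newly past it were 2 and 7. Most gene list calls for whole lists were thus not past the threshold within 50 kb. With ties counted in the middle, a list with all members listed can stay below the upper threshold where most genes have such a peak. Calls that ended within 50 kb may therefore reflect this ceiling, and a loss of enrichment was not told apart from it. At equal lengths, the glial, mesenchymal and cell cycle lists, of 20 genes each, could not pass the lower threshold in ATF2WT with DMSO. With 2522 genes listed there, this holds even with no member listed, so the end of those calls is no check. The calls that ended at equal lengths were, for ATF2WT with DMSO, DLK/LZK-JNK (92.4), integrated stress response (87.8), cytoskeleton (95.4), ribosomal (38.6), glial (39.4), mesenchymal (16.4) and cell cycle (16.1). For JUNWT with DMSO they were MAPK phosphatases (96.8), apoptosis (80.2), p53 (84.6) and ribosomal (96.0), with axon injury newly past (99.8). Within 50 kb they were, for ATF2WT with DMSO, integrated stress response (77.4), ribosomal (86.4), mesenchymal (9.96), cell cycle (43.1) and hepatocyte (59.5), with AP-1 and ATF/CREB newly past (99.05). For JUNWT with DMSO they were AP-1 and ATF/CREB (91.7), DLK/LZK-JNK (88.0), MAPK phosphatases (76.5), apoptosis (94.8), integrated stress response (90.1), immediate-early (91.1), p53 (88.9), cytoskeleton (95.2), pan-neuronal (91.1), pluripotency (7.02), hepatocyte (14.8) and ribosomal (92.9). DLK/LZK-JNK also fell to 69.3 for ATF2WT with vincristine and 91.0 for ATF2AA with DMSO at equal lengths, and within 50 kb to 90.4 for ATF2WT with vincristine, 93.1 for JUNWT with vincristine and 94.5 for JUNAA with DMSO. The cytoskeletal list in ATF2WT with vincristine fell to 42.5 at equal lengths and 84.5 within 50 kb. AP-1 and ATF/CREB in ATF2WT with vincristine fell to 81.3 and 93.5 under these settings. The glial list in ATF2WT with DMSO turned from 1.72 to 97.8 when any peak within 50 kb counted; the cause was not tested. Recovered treatment depth ranged from 40.2 to 86.8 M reads, and what depth limits was not measured.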

Other observations

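The comparison of every ATF2 list with every JUN list was chosen after the data were seen, and the test in the next paragraph before. ATF2 sites overlapped JUNWT more than JUNAA in every pairing of the same treatment. Of ATF2AA peaks with vincristine, 61.9% overlapped JUNWT peaks with DMSO and 34.1% JUNAA peaks with DMSO, and of ATF2AA peaks with DMSO 57.5 and 36.3%. For ATF2WT the shares against the DMSO lists were 47.7 and 26.5% with DMSO and 32.5 and 17.3% with vincristine. Away from gene ends the gap for ATF2AA with vincristine was wider, at 52.8 against 19.7%. With lists cut to 18341 peaks it was 22.1 against 19.2%, and with both restrictions 12.3 against 7.84%.

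ATF2WT sites listed with vincristine only might overlap JUN through gene ends alone, where many factors are found. Of the 24779 such sites away from gene ends, 7.48% overlapped JUNWT vincristine peaks away from gene ends, against at most 0.884% and on average 0.746% in shuffles. The overlap was thus not confined to gene ends. It was lower than at other ATF2WT sites: with gene ends kept, 12.8% of the vincristine-only peaks overlapped JUNWT vincristine peaks, against 42.1% of those shared with DMSO. The vincristine-only peaks overlapped the JUNWT DMSO list in 15.5% of cases. Shuffles do not hold open chromatin constant, and no biological explanation was tested.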
